A study of Rattus norvegicus with 4 samples.

How the data were processed

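Pituitary cells of female rats were measured as messenger RNA by droplet single-cell sequencing (10x Chromium 3' kit) in 4 libraries. Glands of 30 rats were dissected into anterior and posterior lobes, with 1 library each, and 30 other glands were dispersed whole into 1 suspension that was loaded on 2 lanes. The lanes are technical repeats of 1 suspension and were summed for every test.

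The deposited matrix holds counts, as whole UMI counts per gene and cell barcode, for 4 libraries aggregated into 1 file. Per the submitters' processing notes it was made with Cell Ranger 3.1. Whether reads were equalized between libraries on aggregation, the genome build and the annotation were not given in the sources used here, so no gene positions are given. The deposited barcode list, a file of another kind, gives each barcode the suffix of its library per the labels. Genes were matched by the symbols and Ensembl identifiers deposited with the matrix.

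Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, 20381 of 32455. Doublets were scored per library with Scrublet (expected rate 0.06) and 588 barcodes scoring above 0.25 were left out, so that 19793 cells remained. The automatic Scrublet thresholds ranged from 0.231 to 0.597 between libraries, and the common threshold of 0.25 was chosen after these were seen. Counts were scaled to 10000 per cell and logged, and 2000 highly variable genes, 30 principal components, 15 neighbors and Leiden resolution 1.0 gave the clusters (scanpy). All genes of the fixed lists other than cell type markers were left out of the clustering. Clusters were named from a fixed list of markers and keep the ending "-like". A cluster led by cell cycle genes was shared out among classes for the count of cycling cells by correlation with class means over 1000 genes. Marker likelihood was tried first for this step; it gave 11.8% of held-out folliculostellate-like cells their own class, against 98.6% by correlation, and was replaced after its results had been seen. Sub-clusters of folliculostellate-like cells used resolution 0.3, chosen after the data were examined.

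For the tests, UMIs were summed per class and preparation for classes with at least 50 cells in both preparations, which gave 22 sums of 11 classes. In the dissected preparation the anterior library gave folliculostellate-like and hormone cells, the posterior library pituicyte-like and melanotroph-like cells, and both libraries the other classes. The edgeR 4.0.16 quasi-likelihood test (TMM normalization, terms for class and preparation, filterByExpr) was run on 14698 genes, with 10 residual degrees of freedom shared by all classes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and "higher" and "lower" are used of called genes in these comparisons. The named genes had the same direction in both preparations where they were among the largest changes. The SE of a log2 fold change was its size divided by the square root of the F statistic. With 2 preparations the test asks how far these differ relative to the classes, and cells were not treated as replicates. The hormone contrast used the mean of 5 classes, and CPM quoted for hormone cells are means over these classes, while their UMI counts and counting intervals are those of pooled sums. In a test on simulated changes, 99 of 100 genes changed 2-fold and 100 of 100 changed 4-fold passed the adjusted p, as did 11 of 14245 unchanged genes. With the size rule as well, 52% of the genes changed 2-fold, 100% of those changed 4-fold and 0 unchanged genes were called. Only genes above a minimum expected count in the smallest sum were changed. Both preparations had the same simulated levels, with a spread drawn from the fitted dispersion trend. These rates therefore do not hold for genes near 0 counts or for genes that differ between the preparations.

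Fixed lists (astroglial, stem and progenitor, Notch, Wnt, Hippo-YAP, retinoid, junction, transmitter uptake and metabolism, growth factor and cytokine, receptor and calcium, extracellular matrix, complement and antigen presentation, pituitary and hypothalamic transcription factor, lipid and cholesterol, cell cycle, immediate early and stress, and vascular genes) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and contrasts. Some genes belong to more than 1 list, and Slc1a2 did not pass the low-count filter. Lists, markers, the comparisons, their tests and most alternatives were set before the data were examined. So was the rule for naming genes. In each direction it took the 6 largest called changes with at least 50 CPM, the 3 members of each list with the highest CPM, and a fixed set of stem and glial genes. For comparisons of single libraries it took the 6 largest ratios in each direction. Cell type markers, hormone genes, possible free RNA and genes with only a provisional symbol were left out of the 6 largest called changes. Changes called largest are therefore the largest among the remaining genes. Some genes that the rule names are not reported here. List members named outside this rule were chosen after their values were seen. Hormone genes were kept as a measure of free RNA, and a level under 10% of that in the class with most was read as possible free RNA.

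Lobes were compared within classes holding at least 50 cells in both libraries. With 1 library per lobe no test was made; genes are named by size, at least 4-fold with at least 50 UMIs in the higher sum and at least 10% of the class with most in that library. Ratios carry 95% intervals from the exact conditional binomial distribution, and shares of cells carry exact Clopper-Pearson intervals; both cover counting error only. Genes at 0 UMIs on 1 side were set at a floor of 3 counts over the group. List medians were placed among 10000 random lists matched on mean expression. They covered genes with at least 50 UMIs over both libraries, without the limit of 10% of the class with most. Groups of 2 preparations leave no other splits to count.

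Alternatives covered clustering genes, resolution, cell filters, doublets, separate random shares of the UMIs for classes and tests, RLE size factors, DESeq2 1.42.0, no low-count filter, no preparation term, only the compared classes, dissected sums over both libraries, possible free RNA left out and each library left out in turn. Alternatives added after the data were examined left out low-depth pituicyte-like cells, hormone-rich folliculostellate-like cells or the highest cell of each gene, or used marker likelihood for cycling cells. Left out were the barcodes that failed the cell filter, and 2 clusters without a class from the class comparisons.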

Results

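Messenger RNA was counted cell by cell in pituitary glands of female Sprague Dawley rats aged 75 days. The data comprised 4 droplet libraries: 1 of anterior lobes and 1 of posterior lobes, both from the same 30 dissected glands, and 2 lanes loaded from 1 suspension of 30 whole glands. The anterior library held 72754998 unique molecular identifiers (UMIs) in 8134 barcodes and the posterior library 61981865 UMIs in 8550 barcodes. Whole-gland lane 1 held 71490425 UMIs in 8347 barcodes and lane 2 held 63820100 UMIs in 7424 barcodes. After filtering, 5508 anterior cells, 3829 posterior cells, 5541 cells of lane 1 and 4915 cells of lane 2 were kept, with medians of 10234, 10604, 9556 and 9594 UMIs per cell. More than 20% of UMIs were mitochondrial in 45.4% of posterior barcodes, against 27.2% of anterior barcodes and 27.5% and 27.9% in the whole-gland lanes. The series title asks about astroglial and stem cell functions of folliculostellate cells, the non-endocrine cells of the anterior lobe. Each dissected lobe had 1 library and the whole-gland lanes were 1 suspension, so the 2 preparations, dissected and whole, were the replicates (n = 2).

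Known markers gave 21 of 23 cell clusters a class name, written here with the ending "-like" because the labels name no cell type. Folliculostellate-like cells formed 3 clusters. In these, S100b, a calcium-binding protein used as a marker of folliculostellate and glial cells, stood at 947 UMIs of the class scaled to a common total (CPM) in the dissected preparation and 881 in the whole glands. Pituicyte-like cells, the glia of the posterior lobe, formed 2 clusters, and S100b stood there at 612 and 483 CPM. Averaged over the 5 hormone classes, S100b was at 2.07 and 1.61 CPM. Both pituicyte-like clusters shared Igfbp2 among their leading genes, and 1 of them was shallow, with a median of 1956 UMIs per cell. Lactotroph-, somatotroph-, corticotroph-, gonadotroph- and thyrotroph-like cells are called hormone cells here. A cluster led by cell cycle genes such as Top2a and Ube2c held 196 cells and a cluster led by interferon-induced genes such as Isg15 and Mx2 held 31 cells; both were left without a class.

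Folliculostellate-like cells made up 15.5% of the anterior library (852 of 5508 cells, exact 95% binomial interval 14.5 to 16.5%) and 8.54% of the posterior library (327 of 3829 cells, 7.67 to 9.47%). In the whole glands they made up 16.2% (1694 of 10456 cells, 15.5 to 16.9%). Pituicyte-like cells made up 28.7% of the posterior library (1099 cells, 27.3 to 30.2%) and 0.909% of the whole-gland cells (95 cells). The anterior library held 0 of 5508 pituicyte-like cells, which allows a share of up to 0.0545% at 3 counts of the total. Melanotroph-like cells, the Pomc-expressing cells of the intermediate lobe, made up 13.8% of the posterior library (530 cells) and 1.11% of the whole-gland cells, with 0 of 5508 in the anterior library. The 5 hormone classes together made up 77.7% of anterior and 72.4% of whole-gland cells. In the posterior library 1093 of 3829 cells were hormone cells. Lactotroph-like cells were 40.3% of anterior and 11.9% of posterior cells, and somatotroph-like cells were 26.9% and 11.3%. Endothelial-like cells were 1.40% of anterior and 6.24% of posterior cells, macrophage-like cells 3.1% and 7.16%, and fibroblast-like cells 0.763% and 4.15%. Schwann-like cells were 1.67% of the posterior library (64 cells) and 0 of 5508 in the anterior library. With 1 library per lobe no test between libraries was made, and these intervals cover counting error only. A stricter cell filter moved the anterior share of folliculostellate-like cells to 6.45% and the posterior share of pituicyte-like cells to 5.07%. Its lower mitochondrial limit lay below the median mitochondrial share of both classes' clusters, so these shares depend on that limit.

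**Figure D1:**
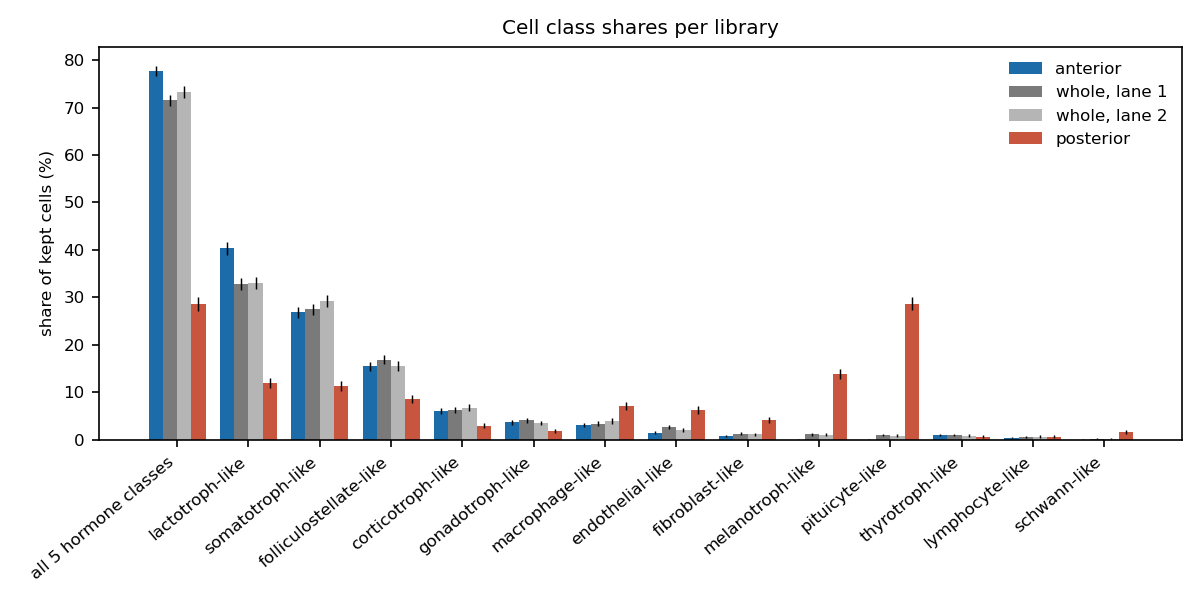
Share of kept cells (%) in each named class, and in the 5 hormone classes together, for the 4 libraries; bars are shares and error bars are exact 95% binomial intervals for counting error. Pituicyte-like cells stand at 28.7% in the posterior library and at 0 in the anterior library, and folliculostellate-like cells at 15.5% and 8.54%.

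The first comparison asked which genes set folliculostellate-like cells apart from the hormone cells of the same lobe. Folliculostellate-like cells had higher levels of astroglial and stem-associated genes in both preparations (n = 2). S100b was 1 of the markers that named the class, so its log2 fold change of 8.73 (SE 0.19) is no independent evidence. The log2 fold change was 7.79 (SE 0.16) for Vim, an intermediate filament gene, and 6.93 (SE 0.13) for Aldoc, a glycolytic enzyme typical of astrocytes. It was 6.33 (SE 0.12) for Sox2 and 6.69 (SE 0.13) for Sox9, both transcription factors of stem and glial cells. Among the genes with the largest increases were Edn3 (ENSRNOG00000007477; 11.09, SE 0.31), which encodes an endothelin, Il33 (ENSRNOG00000016456; 9.76, SE 0.16), Grifin (ENSRNOG00000001251; 9.76, SE 0.23), Mpzl2 (ENSRNOG00000016085; 9.72, SE 0.26) and Fmo1 (ENSRNOG00000034191; 9.69, SE 0.22). The largest decreases were in Resp18 (ENSRNOG00000019704; -4.11, SE 0.22), Caly (ENSRNOG00000018337; -3.85, SE 0.17), Stmn2 (ENSRNOG00000011705; -3.79, SE 0.22), Lhfpl5 (ENSRNOG00000022283; -3.76, SE 0.16), Chga (ENSRNOG00000052549; -3.74, SE 0.20) and Stmn3 (ENSRNOG00000013657; -3.69, SE 0.14). Chga encodes a protein of secretory granules. Among 14698 genes tested with edgeR, 3364 were higher and 1748 lower in folliculostellate-like cells. With possible free RNA left out, 2667 were higher and 1717 lower. Hormone RNA was present in every class: Prl stood at 39838 CPM in dissected and 33148 CPM in whole-gland folliculostellate-like cells, against 480469 and 505734 CPM in lactotroph-like cells. Most of this Prl lay in few cells: 299135 of 342947 anterior UMIs in the 78 cells of sub-cluster 3 (below) and 429668 of 505904 whole-gland UMIs in 149 cells, and the other anterior folliculostellate-like cells stood at 6847 CPM.

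Of the astroglial list, 25 members were tested against hormone cells. Of these, 21 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 8.80e-11). The remaining members, among them Slc1a2, did not pass the low-count filter and are outside these counts. Some listed genes were near absent: Slc1a2 reached at most 1.88 CPM in any folliculostellate-like sub-cluster (below), and Fabp7, Bcan and Scrg1 at most 0.235 CPM. Gja1, which encodes a connexin of gap junctions, was higher by 8.31 (SE 0.15), the water channel gene Aqp4 by 8.60 (SE 0.28), the glutamate transporter gene Slc1a3 by 5.44 (SE 0.13) and Glul, which encodes glutamine synthetase, by 3.86 (SE 0.09). Apoe was higher by 7.30 (SE 0.25), while Clu stood at 0.72 (SE 0.12), under the size required, and Gjb6 was lower by 1.19 on the log2 scale. Gfap, the classical astrocyte filament gene, passed the test at 3.44 (SE 1.15) but reached only 0.116 and 0.786 CPM in folliculostellate-like cells. It missed the threshold at 2.85 without whole-gland lane 1. Of the stem and progenitor list, 20 of 22 tested members were higher and 0 lower, also adjusted over the list alone (adjusted p = 5.07e-11). Klf4 was higher by 3.63 (SE 0.17), Hes1 by 6.65 (SE 0.12), Cd9 by 5.71 (SE 0.15) and Aldh1a1 by 6.70 (SE 0.16). Nes, the nestin gene, passed at 3.89 (SE 0.77) with at most 0.917 CPM. Lhx3, a pituitary transcription factor gene, was higher by 1.10 (SE 0.10) and fell under the size required with doublets kept, at 0.96.

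Notch pathway genes were higher in 12 and lower in 1 (Hes6) of 16 members tested (adjusted p = 8.58e-07), with Hey2 at 9.15 (SE 0.16) and Nrarp at 7.91 (SE 0.21). Genes of the Hippo-YAP pathway were higher in 10 of 11 (adjusted p = 8.58e-07), with Cyr61 at 6.90 (SE 0.16) and Amotl2 at 6.29 (SE 0.12). Wnt pathway genes were higher in 11 and lower in 1 (Wnt4) of 16 (adjusted p = 1.23e-04), with Wnt5a at 7.41 (SE 0.14). Junction genes were higher in 11 of 15 (adjusted p = 1.07e-04), although Epcam stood at 0.28 (SE 0.15, adjusted p = 0.104). Extracellular matrix genes were higher in 19 and lower in 1 (Lamb1) of 22 (adjusted p = 4.32e-07), with Timp3 at 7.29 (SE 0.21) and Timp1 at 5.68 (SE 0.13). Genes of the vascular list were higher in 10 of 12 (adjusted p = 1.89e-04). For the lists named so far the counts adjusted over the list alone were the same, and all 8 calls held with an estimated correlation, with adjusted p = 0.0473 for the Wnt list as the highest.

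Of the other lists, all but the lipid and cholesterol list, which had no call, lost their call against hormone cells when the correlation was estimated. Growth factor and cytokine genes were higher in 23 and lower in 1 (Il18) of 27 (adjusted p = 1.84e-07; adjusted p = 0.0667 with an estimated correlation), with Igfbp5 at 7.28 (SE 0.17) and Ptn, which encodes pleiotrophin, at 6.70 (SE 0.24). Receptor and calcium genes were higher in 17 of 24 (adjusted p = 1.23e-04; adjusted p = 0.0667 with an estimated correlation), with S1pr1 at 7.34 (SE 0.22) and Adcyap1r1 at 5.96 (SE 0.15). Retinoid genes were higher in 6 of 10 (adjusted p = 0.00185; adjusted p = 0.0521 with an estimated correlation). Transmitter uptake genes were higher in 12 and lower in 3 (Slc1a1, Slc6a6 and Slc38a1) of 20 (adjusted p = 0.00275; adjusted p = 0.0667 with an estimated correlation), with a median of 1.78, or 2.37 with the member at 0 counts set at its bound. Pituitary and hypothalamic transcription factors were higher in 10 and lower in 1 of 14 (adjusted p = 0.00185; adjusted p = 0.0667 with an estimated correlation), and Pou1f1 was the lower one. Complement and antigen presentation genes were higher in 11 of 17 (adjusted p = 3.32e-04; adjusted p = 0.153 with an estimated correlation), with Anxa1 at 7.21 (SE 0.13). Cd74, RT1-Da and RT1-Ba, among the higher ones, stood under 10% of their level in the class with most. Immediate early genes were higher in 14 of 14 (adjusted p = 1.84e-07; adjusted p = 0.0798 with an estimated correlation), with Btg2 at 2.17 (SE 0.14), Junb at 1.83 (SE 0.10) and Fos at 1.55 (SE 0.15). Median mitochondrial shares of UMIs were 10.87% to 11.68% in the folliculostellate-like clusters. They were 4.77% to 8.43% in lactotroph-, somatotroph- and corticotroph-like clusters, and 11.11% and 11.54% in gonadotroph- and thyrotroph-like ones. Cell cycle genes were higher in 9 of 14 (adjusted p = 0.0412; adjusted p = 0.338 with an estimated correlation), and the call also ended without lane 2 (0.271), without the posterior library (0.0554) and without the hormone-rich cells of sub-cluster 3 (0.116). The class sums left out the 196 cells of the cluster led by cell cycle genes. By correlation 108 of these resembled lactotroph-, 53 somatotroph- and 22 folliculostellate-like cells most. Cells rich in this RNA were thus left out unevenly, and the cell cycle list does not measure how often the classes divide. Lipid and cholesterol genes were higher in 3 (Lpl, Plin2 and Srebf1) and lower in 2, including Fasn, of 16, and the list missed the threshold (adjusted p = 0.229). For each of these lists the counts adjusted over the list alone were the same.

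The second comparison set folliculostellate-like cells against pituicyte-like cells, the other glia-like class of the gland. Sox2 and Sox9 differed by less than the size required, while other genes differed by several orders of magnitude, in both preparations (n = 2). Sox2 differed by 0.12 (SE 0.14, adjusted p = 0.505) and Sox9 by -0.05 (SE 0.12, adjusted p = 0.771) on the log2 scale; the sign for Sox2 turned without the anterior library (-0.05) and that for Sox9 turned without lane 2 (0.03) and without the posterior library (0.01). Higher in folliculostellate-like cells were Gpha2 (ENSRNOG00000021020; 9.24, SE 0.50), which encodes a glycoprotein hormone subunit, Guca2b (ENSRNOG00000008979; 8.80, SE 0.73) and Edn3 (8.80, SE 0.49). Nr2f1 (ENSRNOG00000014795) was 518-fold higher (95% counting interval 92.8 to 20485), with 1 UMI in pituicyte-like cells, and Grifin 479-fold higher (132 to 3958), with 2 UMIs. Lower were Csap1 (ENSRNOG00000049151; -10.93, SE 0.51), Grik3 (ENSRNOG00000008992; 4030-fold, 1378 to 19550), a kainate receptor gene, and Acsbg1 (ENSRNOG00000011381; 5871-fold, 1053 to 232003), which encodes an acyl-CoA synthetase of glia. Galp (ENSRNOG00000022129), Nkx2-4 (ENSRNOG00000012647) and F5 (ENSRNOG00000057855) had 0 UMIs in folliculostellate-like cells and were at least 2457-fold, 1081-fold and 706-fold lower at a floor of 3 counts over the group. Nkx2-4 is a homeobox gene and F5 encodes a coagulation factor. With edgeR, 2552 genes were higher and 1877 lower, or 2047 and 1749 with possible free RNA left out. In the main setting the number called was 4429 in all. The number was 2882 without the anterior library and 2873 without the posterior library.

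The astroglial list went both ways between these classes: of 25 tested members, 4 (Sparcl1, Aldoc, Fgfr3 and Vim) were higher and 11 lower in folliculostellate-like cells, also adjusted over the list alone (adjusted p = 0.0310; adjusted p = 0.289 with an estimated correlation). Aldoc was higher by 2.64 (SE 0.20) and Vim by 1.80 (SE 0.21). Gfap was lower by 5.92 on the log2 scale (SE 0.47), with 46.8 and 26.8 CPM in pituicyte-like cells, Cst3 by 2.66 (SE 0.28) and Gja1 by 1.49 (SE 0.11). Apoe stood at -0.45 (SE 0.37, adjusted p = 0.324), Aqp4 at 0.52 (SE 0.22, adjusted p = 0.0508) and Glul at 0.43 (SE 0.11), under the size required. S100b stood at 0.84 (SE 0.22) and Slc1a3 at -0.99 (SE 0.13), close to that size; Slc1a3 reached it without the posterior library, at -1.14. The list also missed the threshold when classes and sums came from separate random shares of the UMIs (0.0595) and when dissected sums ran over both libraries (0.0652).

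Stem and progenitor genes were higher in 15 and lower in 2 (Prrx2 and Lgr4) of 22 tested members, also adjusted over the list alone (adjusted p = 1.26e-06; adjusted p = 0.0473 with an estimated correlation). Klf4, a pluripotency-associated factor, was higher by 5.48 (SE 0.34), Hes1 by 2.11 (SE 0.17), Cd9 by 1.57 (SE 0.22) and Aldh1a1 by 4.42 (SE 0.23). A response to dispersal stays open for immediate early genes (below). Whether it also raised Klf4 or Cyr61 in folliculostellate-like cells was not tested. Nes stood at -1.02 (SE 0.58, adjusted p = 0.149), with at most 3.50 CPM in either class. Notch pathway genes were higher in 9 and lower in 0 of 16 (adjusted p = 1.23e-04; adjusted p = 0.0667 with an estimated correlation), with Hey2 at 6.82 (SE 0.24) and Nrarp at 5.76 (SE 0.33). Hippo-YAP genes were higher in 4 (Cyr61, Amotl2, Tead3 and Ctgf) of 11 (adjusted p = 0.0109; adjusted p = 0.0667 with an estimated correlation). Cyr61 was higher by 5.72 (SE 0.28); Ctgf, at 1.32 (SE 0.29), stood under 10% of its level in the class with most. Pituitary and hypothalamic transcription factors were higher in 11 and lower in 2 of 14 (adjusted p = 3.03e-04; adjusted p = 0.144 with an estimated correlation), with a median of 5.81, or 4.86 with 1 member at 0 counts set at its bound. Lhx3 was higher by 6.11 (SE 0.30) and Six6 by 3.60 (SE 0.29), and the lower ones were Tbx3 (-7.45, SE 0.23), a regulator of hypothalamic and infundibular development, and Six3 (-1.10, SE 0.14; -0.88 without the anterior library, adjusted p = 0.153).

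Immediate early genes were higher in 13 of 14 members tested and lower in 0, also adjusted over the list alone (adjusted p = 2.02e-13; adjusted p = 0.0336 with an estimated correlation). Fos was higher by 4.57 (SE 0.26), Junb by 5.43 (SE 0.19) and Btg2 by 4.67 (SE 0.24). The median mitochondrial share of UMIs also differed, at 14.40% and 14.99% in the pituicyte-like and 10.87% to 11.68% in the folliculostellate-like clusters. Transmitter uptake genes were lower in 10 and higher in 3 of 20 (adjusted p = 0.0109; adjusted p = 0.143 with an estimated correlation), with a median of -1.00, or -1.16 with 1 member set at its bound. Slc6a6, the taurine transporter gene, was lower by 6.50 on the log2 scale (SE 0.46) and Ldhb by 1.99 (SE 0.20); the 3 higher ones were Slc6a8, Slc38a1 and Slc38a2. Complement and antigen presentation genes were higher in 7 and lower in 0 of 17 (adjusted p = 0.0338; adjusted p = 0.365 with an estimated correlation), with Anxa1 at 4.06 (SE 0.18). Of the 7, RT1-Ba, RT1-Da, Cd74 and Serping1 were among those that stood under 10% of their level in the class with most, and the call ended without lane 1 (0.0596) and without the anterior library (0.0672). Cell cycle genes were higher in 5 of 14, or 6 adjusted over the list alone (adjusted p = 0.0122; adjusted p = 0.265 with an estimated correlation). These 5 were Cenpf, Top2a, Mcm6, Mcm5 and Cdk1, and the call ended without lane 2 (0.0931) and without the posterior library (0.132). The sums again left out the cell cycle cluster, of which 22 cells resembled folliculostellate-like and 0 pituicyte-like cells most. The list therefore does not measure how often these classes divide. Mcm6 was higher by 2.27 (SE 0.33) and missed the threshold without the posterior library, at 1.40.

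Several lists held large differences in both directions and no call. Growth factor and cytokine genes were higher in 10 and lower in 10 of 27, or 10 and 12 adjusted over the list alone (adjusted p = 0.700). Igfbp5 was higher by 4.31 (SE 0.30) and Igfbp2 lower by 7.38 on the log2 scale (SE 0.62); both encode binding proteins of insulin-like growth factors. Ptn was lower by 1.11 (SE 0.33) and missed the threshold without the anterior library (-0.67, adjusted p = 0.418). The list's median was -0.68, its mean 0.33 and the test pointed down. Receptor and calcium genes were higher in 12 and lower in 5 (S1pr1, Npr2, Adra2a, Lpar1 and Adora1) of 24 (adjusted p = 0.257; median 1.44, or 1.16 with 3 members set at their bounds), with Adcyap1r1 higher by 5.63 (SE 0.26) and S1pr1 lower by 1.33 (SE 0.13). Retinoid genes were higher in 5, including Aldh1a1, Aldh1a3, Rarb and Rdh10, and lower in 3 (Stra6, Dhrs3 and Crabp1) of 10 (adjusted p = 0.700): Stra6, a retinol uptake receptor gene, was lower by 10.04 on the log2 scale (SE 0.37). The test's direction turned without lane 2. Junction genes were higher in 6 and lower in 5 (Cldn10, Ocln, Gja1, Marveld2 and F11r) of 15 (adjusted p = 0.985; median -0.06, mean 0.81, test down), with Epcam higher by 5.26 (SE 0.27) and Cldn10 lower by 3.56 (SE 0.21). Extracellular matrix genes were higher in 5 (Timp1, Nid1, Lgals3, Lamb1 and Sparc) and lower in 6 of 22 (adjusted p = 0.376; median -0.17, mean 0.13, test down), with Timp1 higher by 5.52 (SE 0.24). Wnt genes were higher in 4 (Fzd3, Tcf7l1, Axin2 and Lef1) and lower in 4 (Sfrp1, Dkk3, Fzd2 and Lrp6) of 16, or 5 and 4 adjusted over the list alone (adjusted p = 0.463; median 0.76, mean -0.07, test up), with Sfrp1, a secreted Wnt antagonist, lower by 4.23 (SE 0.23). Genes of the vascular list were higher in 4 (Ednrb, Angpt2, Cav1 and Esm1) and lower in 4 (Mfsd2a, Ocln, Slc2a1 and Apln) of 12, or 5 and 4 adjusted over the list alone (adjusted p = 0.858; median 0.57, mean 1.42, test down), with Mfsd2a lower by 4.14 (SE 0.21); the direction of the test turned without the anterior library. Lipid and cholesterol genes were higher in 4, including Insig1, Fabp5 and Hmgcs1, and lower in 6 of 16 (adjusted p = 0.0661), with Srebf1 lower by 3.74 (SE 0.17), and the list passed without lane 2 (0.0338) and without the posterior library (0.0229). Counts adjusted over the list alone were the same where none is given.

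**Figure D2:**
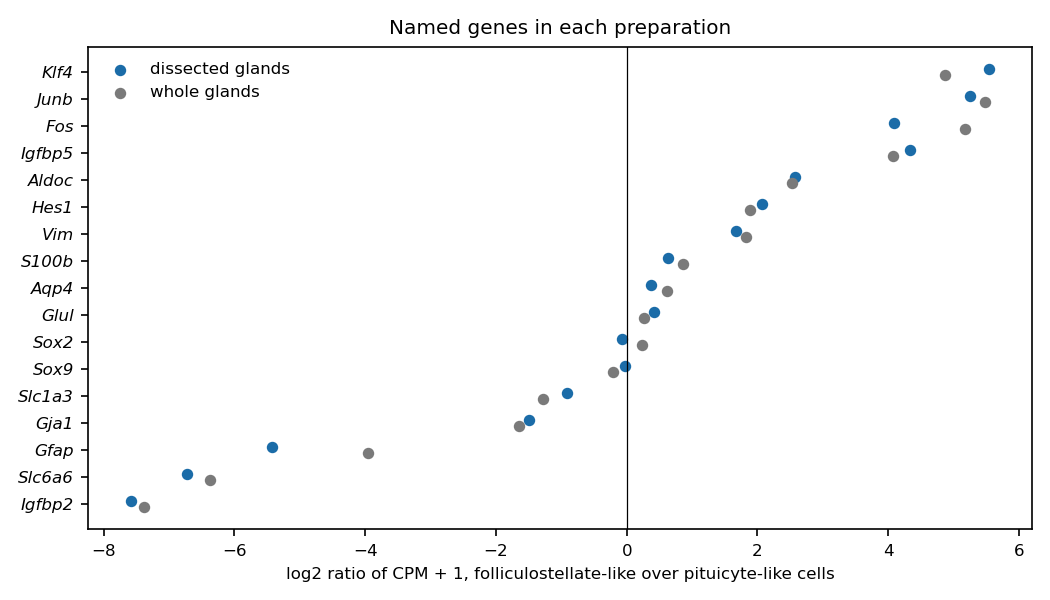
Log2 ratio of folliculostellate-like over pituicyte-like cells, computed on CPM + 1, for a set of named genes; each gene has 1 point for the dissected and 1 for the whole glands. Sox2 and Sox9 lie near 0 in both preparations, Klf4 lies at 5.54 and 4.87, and Igfbp2 lies at -7.58 and -7.39.

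The third comparison used pituicyte-like cells as the glial reference against the same hormone cells. Pituicyte-like cells had high astroglial gene levels in both preparations (n = 2): Gfap was higher by 9.36 (SE 0.49), Gja1 by 9.80 (SE 0.15), Aqp4 by 8.08 (SE 0.35), Slc1a3 by 6.43 (SE 0.14) and S100b by 7.89 (SE 0.20). Sox2 was higher by 6.21 (SE 0.14) and Sox9 by 6.73 (SE 0.15). The genes with the largest increases were Ppp1r1b (ENSRNOG00000028404; 13.24, SE 0.33), a phosphatase regulator of dopamine signalling, Cldn10 (ENSRNOG00000010085; 12.46, SE 0.26), Fndc3c1 (ENSRNOG00000002451; 12.40, SE 0.37) and Csap1 (11.98, SE 0.34). Tekt3 (ENSRNOG00000027212), a ciliary tektin gene, was 14075-fold higher (95% counting interval 3891 to 116310), with 2 UMIs in hormone cells. Msmp (ENSRNOG00000043023) was 14632-fold higher (2620 to 578530), with 1 UMI in hormone cells. Lower were Asb4 (ENSRNOG00000009197; -6.36, SE 0.30), Dner (ENSRNOG00000016640; -6.22, SE 0.32), Pitx1 (ENSRNOG00000011423; -6.20, SE 0.26), a pituitary transcription factor gene, 5330417C22Rik (ENSRNOG00000020272; -6.20, SE 0.24) and Scg2 (ENSRNOG00000015055; -6.18, SE 0.27), a secretory granule gene. Nell2 (ENSRNOG00000006235) was 77.5-fold lower (21.4 to 640), with 2 UMIs in pituicyte-like cells. With edgeR, 3014 genes were higher and 2096 lower, or 2490 and 2045 with possible free RNA left out.

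Astroglial genes were higher in 24 of 25 tested members, also adjusted over the list alone (adjusted p = 5.52e-16; adjusted p = 0.0336 with an estimated correlation), and Gjb6 stood at -0.53. This list alone kept its call with an estimated correlation in this comparison. Stem and progenitor genes were higher in 11 and lower in 6 of 22 (adjusted p = 0.0978), with Hes1 higher by 4.54 (SE 0.15), Cd9 higher by 4.14 (SE 0.17) and Klf4 lower by 1.85 (SE 0.29). The list passed the threshold without the posterior library (0.0193). Immediate early genes were lower in 12 and higher in 2 (Hspb1 and Ier3) of 14 (adjusted p = 9.31e-07; adjusted p = 0.0667 with an estimated correlation), with Junb at -3.60 (SE 0.16), Fos at -3.02 (SE 0.22) and Btg2 at -2.49 (SE 0.20). The median mitochondrial share of UMIs differed here too, at 14.40% and 14.99% in the pituicyte-like and 4.77% to 11.54% in the hormone cell clusters. Transmitter uptake genes were higher in 13 and lower in 1 (Slc38a1) of 20 (adjusted p = 8.58e-07; adjusted p = 0.0667 with an estimated correlation), with Slc6a6 at 5.16 (SE 0.24) and Ldhb at 5.77 (SE 0.14). Growth factor and cytokine genes were higher in 19 and lower in 1 (Nppc) of 27 (adjusted p = 2.88e-07; adjusted p = 0.0729 with an estimated correlation), with Igfbp2 at 10.54 (SE 0.37) and Ptn at 7.81 (SE 0.24). Extracellular matrix genes were higher in 17 and lower in 1 (Lamb1) of 22 (adjusted p = 4.28e-07; adjusted p = 0.0667 with an estimated correlation), with Timp3 at 6.51 (SE 0.21) and Timp1 at 0.16 (SE 0.18, adjusted p = 0.480). Vascular list genes were higher in 7 and lower in 1 (Cav1) of 12 (adjusted p = 0.00327; adjusted p = 0.0667 with an estimated correlation), with Mfsd2a at 9.24 (SE 0.28) and Ocln at 3.82 (SE 0.13).

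Hippo-YAP genes were higher in 10 of 11 (adjusted p = 2.88e-04; adjusted p = 0.183 with an estimated correlation), with Amotl2 at 3.51 (SE 0.22). Wnt genes were higher in 11 and lower in 2 (Wnt4 and Axin2) of 16 (adjusted p = 0.00139; adjusted p = 0.144 with an estimated correlation; median 3.04, or 3.30 with 1 member at its bound), with Fzd2 at 10.24 (SE 0.29) and Sfrp1 at 8.88 (SE 0.27). Retinoid genes were higher in 6 of 10 (adjusted p = 0.00408; adjusted p = 0.0798 with an estimated correlation), with Stra6 at 10.60 (SE 0.28). Notch genes were higher in 10 and lower in 1 (Jag2) of 16 (adjusted p = 0.0157; adjusted p = 0.289 with an estimated correlation); Nrarp, at 2.14 (SE 0.59), and Hey2, at 2.34 (SE 0.78), stood under 10% of their level in the class with most. Both had 0 UMIs in the 95 whole-gland pituicyte-like cells, so these changes rest on the posterior library. Junction genes were higher in 9, or 10 adjusted over the list alone, and lower in 4 of 15 (adjusted p = 0.0308; adjusted p = 0.147 with an estimated correlation); the lower ones were Epcam (-4.98, SE 0.25), Cldn3, Cldn4 and Cldn7. Complement and antigen presentation genes were higher in 9 and lower in 1 (RT1-A2) of 17 (adjusted p = 0.0293; adjusted p = 0.365 with an estimated correlation), with B2m at 1.15 (SE 0.10). Receptor and calcium genes were higher in 6 and lower in 3 (Npr1, Itpr2 and Ednra) of 24 (adjusted p = 0.0683; median 0.57, or 0.66 with 3 members at their bounds) and passed without the posterior library (0.0193). Pituitary and hypothalamic transcription factors were higher in 3 (Tbx3, Six3 and Vax1) and lower in 7 of 14 (adjusted p = 0.154; median -3.55, or -1.50 with 1 member at its bound), with Tbx3 at 8.98 (SE 0.18) and Lhx3 at -5.01 (SE 0.32). Lipid and cholesterol genes were higher in 6 and lower in 4, including Insig1 and Fabp5, of 16 (adjusted p = 0.752), with Srebf1 at 5.15 (SE 0.14). The cell cycle list was again tested without the cell cycle cluster, of which 108 cells resembled lactotroph-, 53 somatotroph- and 0 pituicyte-like cells most. Its values therefore do not show which class divides more. Cell cycle genes were higher in 1 (Mki67) and lower in 2 (Mcm6 and Tyms) of 14 (adjusted p = 0.700; median 0.49, mean 0.43, test down); Mcm6 (-1.62) missed the threshold without the posterior library (-0.72), and Tyms (-1.17) fell under the size required without the anterior library (-0.93) and missed the threshold without the posterior library (-0.90). Counts adjusted over the list alone were the same where none is given.

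The anterior and the posterior library were compared within the classes present in both. The posterior library also held 1093 hormone cells and 530 melanotroph-like cells, so it was not posterior lobe alone. How many cells of the shared classes came from other lobes was not tested, and a difference between libraries need not be one between lobes. Endothelial-like cells of the posterior library carried water channel and carbonic anhydrase RNA that anterior ones had little of. Aqp1 stood at 1397 CPM in the posterior and 31.1 CPM in the anterior library, 44.9-fold apart (95% counting interval 30.8 to 68.3), with UMIs in 194 of 239 posterior cells. Car4, the membrane carbonic anhydrase gene, had 417 UMIs in 108 posterior cells and 0 in 77 anterior cells, at least 66.9-fold higher at a floor of 3 counts over the group. Wfdc1 was 107-fold higher (36.4 to 520), Akr1cl 52.5-fold (14.4 to 436) and Clic5 40.4-fold (13.7 to 197), in 133, 97 and 117 posterior cells. In the anterior library the leading genes were the hemoglobin genes Hbb (67.3-fold, 17 cells), Hba-a3 (at least 88.6-fold, 15 cells) and Hba-a2, with 2 gene identifiers, at 17.6-fold and 17.5-fold. Ccl19 and Slpi rested on few cells: 134 of 144 Ccl19 UMIs lay in 1 cell and Slpi lay in 3 cells, and Cilp (47.4-fold higher in the posterior library, 13.0 to 394) lay in 24 cells. By the size rule 135 genes were higher in the posterior and 19 in the anterior library. The libraries also differed in which cluster gave the class: 201 of 239 posterior cells came from the cluster led by Aqp1, which held 0 anterior cells, and the 77 anterior cells came from a cluster whose leading genes included Hbb and Hba-a2. Within these cells the growth factor list had a median log2 ratio of anterior over posterior of -1.64, below the 95% range of matched random lists (-0.25 to 0.19). Also below their ranges were the Wnt (-1.21), vascular (-0.85), junction (-0.75), Notch (-0.65), stem (-0.65), astroglial (-0.36), extracellular matrix (-0.35) and immediate early lists (-0.25).

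Macrophage-like cells of the posterior library carried more Lyve1, a hyaluronan receptor gene of perivascular macrophages: 207 CPM against 19.6 CPM, 10.6-fold (6.69 to 17.7), with UMIs in 105 of 274 cells. Inka1 was 29.4-fold higher (5.09 to 1178) and had UMIs in 48 cells. Avp, the vasopressin gene of hypothalamic axons, met the size rule (at least 12.5-fold), but its 38.8 CPM in posterior macrophage-like cells does not set the class apart: in the posterior library Avp stood at 43.3 CPM in endothelial-like, 39.3 CPM in fibroblast-like and 72.6 CPM in pituicyte-like cells. Siglech (at least 36.6-fold, 4 cells) and Jchain (at least 36.3-fold, 7 cells) rested on few cells, and 509 of 529 Tshb UMIs lay in 1 cell. In the anterior library Prl was 11.4-fold higher (11.2 to 11.7), at 55427 CPM, and stood at 11.5% of its level in lactotroph-like cells. Klk1 (18.4-fold), Olfm1 (8.30-fold), Sparcl1 (10.3-fold) and Cxcl9 (11.4-fold) no longer met the size rule without the cell with most UMIs, and 432 of 437 Guca2b UMIs (476-fold) lay in 1 cell. By the size rule 39 genes were higher in the posterior and 23 in the anterior library; leaving out the highest cell of each gene gave 49 and 10. Of 274 posterior cells, 192 came from the cluster led by Ctss and Ccl3, and of 171 anterior cells, 157 came from the cluster led by RT1-Db1 and RT1-Bb. The complement and antigen presentation list had a median log2 ratio of 0.32, above the range of matched random lists (-0.49 to 0.15). The astroglial (0.45), stem (0.42) and immediate early lists (0.16) also lay above their ranges and the receptor and calcium list (-0.67) below. List medians took in genes at any level relative to the class with most. Free RNA of other classes may therefore enter these medians and was not separated from RNA of macrophage-like cells.

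Folliculostellate-like cells were compared with 852 anterior and 327 posterior cells. Tfap2c, a transcription factor gene, had 82 UMIs in 21 of 327 posterior cells and 0 in 852 anterior cells (at least 59.4-fold). Gda, which encodes guanine deaminase, was 48.5-fold higher in the posterior library (15.9 to 241; 20 cells), and Slc16a10 55.4-fold (14.6 to 470; 18 cells). Chia had 852 posterior UMIs, of which 839 lay in 1 cell, so its fold of at least 617 describes that cell. Sntn had 73 of 107 UMIs and Tmem212 (97.8-fold, 32.8 to 480) 66 of 135 UMIs in 1 cell. Higher in the anterior library were Krt25 (12.9-fold, 3.40 to 109; 31 cells), Pou1f1 (8.47-fold, 5.21 to 14.7; 104 cells), Pycr1 (7.94-fold, 3.92 to 18.7; 64 cells), Grik1 (7.27-fold, 2.99 to 23.0; 41 cells), Ifit3 (6.44-fold, 2.63 to 20.5; 17 cells) and Gal (5.24-fold, 3.92 to 7.14; 93 cells). Pou1f1 stood at 10.0%, Gal at 12.1% and Krt25 at 12.2% of their level in the class with most, and these 3, with Ifit3, no longer met the size rule without the cell with most UMIs. Of the 313 anterior Pou1f1 UMIs, 258 lay in the 78 hormone-rich cells of sub-cluster 3 (below), at 117 CPM against 5.34 to 11.5 CPM in the other anterior sub-clusters, so its fold comes mostly from these cells. By the size rule 56 genes were higher in the posterior and 13 in the anterior library; leaving out the highest cell of each gene gave 26 and 8, and leaving out the hormone-rich cells gave 65 and 3. The junction list had a median log2 ratio of -0.59, below the range of matched random lists (-0.20 to 0.12), and the immediate early list -0.29 (-0.11 to 0.06). Also below their ranges were the vascular (-0.50), Hippo-YAP (-0.31), Wnt (-0.26), stem (-0.24) and lipid lists (-0.22), and above them the astroglial (0.19), transcription factor (0.16) and Notch lists (0.14). The libraries also differed in sub-clusters: sub-cluster 4 (below), where the junction gene Cldn3 stood at 145 CPM against 2.55 CPM in sub-cluster 1, gave 27.8% of posterior and 16.0% of anterior cells. Lists with under 5 members at 50 UMIs or more over both libraries were not placed among random lists: retinoid, transcription factor and cell cycle in endothelial-like cells, and these with Wnt, Hippo-YAP, junction and vascular in macrophage-like cells. The other lists not given here lay within their ranges.

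Separate preparations gave similar profiles of folliculostellate-like cells. Across 22772 genes, which are not independent replicates, log2(CPM + 1) correlated at r = 0.995 between the anterior library and the whole glands, and 28 of 10674 genes with at least 100 UMIs differed by more than 2-fold. Between the whole-gland lanes r was 0.993 and 6 of 9481 genes differed by more than 2-fold. Between the posterior library and the whole glands r was 0.981 and 310 of 10190 genes differed by more than 2-fold. The lanes held 16.9% (15.9 to 17.9%) and 15.5% (14.5 to 16.5%) folliculostellate-like cells.

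Cycling cells were counted as cells with a UMI of Mki67 or Top2a, 2 genes of dividing cells, after thinning to 2000 UMIs per cell. Shallower cells were left out, so the shares describe deeper cells only. Left out were 264 posterior pituicyte-like cells, and 38 anterior, 38 posterior and 117 whole-gland folliculostellate-like cells. Folliculostellate-like cells held 1.22% (10 of 821, exact 95% interval 0.586 to 2.23%) in the anterior library, 1.38% (4 of 289, 0.378 to 3.51%) in the posterior library and 1.63% (26 of 1592, 1.07 to 2.38%) in the whole glands. Hormone cells held 0.911% (0.649 to 1.24%), 0.743% (0.321 to 1.46%) and 1.23% (0.989 to 1.50%), so the intervals of the classes overlapped in each library. Pituicyte-like cells held 1.08% (9 of 835, 0.494 to 2.04%) in the posterior library and 0 of 86 in the whole glands. That 0 sets no limit on dividing cells, since without thinning 6 of 95 whole-gland cells (6.32%, 2.35 to 13.2%) had a UMI. Macrophage-like cells stood at 1.24% (2 of 161, 0.151 to 4.42%) in the anterior library, 5.22% (2.89 to 8.61%) in the posterior library and 5.29% (3.22 to 8.14%) in the whole glands. Median depths before thinning were 6535 UMIs in anterior folliculostellate-like and 11656 in anterior hormone cells. The cell cycle cluster was shared out by correlation with class means, and of its 196 cells 108 went to lactotroph-, 53 to somatotroph-, 22 to folliculostellate- and 0 to pituicyte-like cells. Assigning them by marker likelihood, which was tried first, gave 0.491% for anterior folliculostellate-like and 9.18% (9 of 98) for whole-gland pituicyte-like cells. Without thinning the anterior folliculostellate-like share was 3.49%. A UMI of either gene may also come from free RNA, which was not separated from division here.

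Folliculostellate-like cells fell into 4 sub-clusters, described by their leading genes. Sub-cluster 1, with Cxcl10, Cxcl1, Socs3 and Icam1 among its leading genes, held 50.1% (46.7 to 53.5%) of the folliculostellate-like cells of the anterior library, 37.6% (32.3 to 43.1%) of the posterior library and 44.7% of the whole glands. Sub-cluster 2, with Agt, Hes5 and Gpha2, held 24.8% (21.9 to 27.8%), 33.0% (28.0 to 38.4%) and 33.1%. Sub-cluster 3, with Prl, Gh1, Chgb and Scg2, held 9.15% (7.30 to 11.3%), 1.53% (0.498 to 3.53%) and 8.80%; its median of 20587 UMIs was the highest of the 4. Sub-cluster 4, with Krt17, Krt18, Cldn4 and Thbs1, held 16.0% (13.6 to 18.6%), 27.8% (23.0 to 33.0%) and 13.4%.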

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

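Of the tests in this part, the share of cells led by Prl and the ratio of Pomc to Chia were set before their results were seen; the tests on free hormone RNA, anterior cells, whole-gland Chia, the single cell, and both tests on immediate early genes were chosen only after the result was seen.

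Barcodes that the cell filter left out were not used in any comparison. In those of the posterior library, Avp stood at 184 CPM (2043 UMIs) and Oxt at 81.6 CPM (906 UMIs), against 28.8 and 18.4 CPM in kept posterior cells. In those of the anterior library both genes had 0 UMIs. In the whole-gland lanes Avp stood at 45.0 and 48.5 CPM and Oxt at 23.3 and 53.1 CPM. Hemoglobin genes took over 50% of the UMIs in 10 anterior, 17 posterior, 9 lane 1 and 13 lane 2 barcodes. The cluster led by interferon-induced genes such as Isg15, Mx2 and Rsad2 held 31 cells. No explanation was tested for these signals.

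Sub-cluster 3 of the folliculostellate-like cells carried Prl and Gh1. Prl stood at 135377 CPM in its anterior cells and 6847 CPM in the other anterior folliculostellate-like cells, a ratio of 19.8. Since Prl is a leading gene of the sub-cluster, this ratio restates the pattern and decides nothing. Its 78 cells among 852 anterior folliculostellate-like cells held 299135 of 342947 Prl UMIs and 3953 of 7225 Pomc UMIs. In the whole glands 149 of 1694 cells held 429668 of 505904 and 14351 of 20873. Free RNA spread evenly over droplets would not gather in so few cells, so these values argue against it for these genes. Free RNA spread unevenly was not tested and stays open. Droplets holding a folliculostellate-like cell and a hormone cell also stay open. Prl led in 54.6% of the sub-cluster's cells (exact 95% interval 47.9 to 61.2%), against a 47.8% lactotroph-like share of hormone cells. This lay within the tolerance set beforehand, although the interval lay above that share. Free RNA rich in Prl could also make Prl lead, so the share cannot tell the 2 explanations apart. The sub-cluster's median of 21905 UMIs in the anterior library was above the 17599.5 UMIs obtained by summing the medians of both cell types, as were 20844 and 18626 in the whole-gland lanes (16955 and 17017.5), while the 5 posterior cells, at 19806, lay below their sum of 25579. No biological explanation was tested.

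Chia stood out in posterior folliculostellate-like cells. Without the cell with most UMIs, which held 839, 13 UMIs remained, so the pattern rests on 1 cell. RNA of melanotroph-like cells is unlikely to be the source of the 839 UMIs in that cell. Over all posterior folliculostellate-like cells with Chia, Pomc UMIs per Chia UMI were 0.00261 of those in melanotroph-like cells. That cell dominates the ratio, which therefore says nothing about the source of the other 13 UMIs. Other explanations cannot be told apart from a single cell, because that cell decides their values. These are anterior cells carried over (posterior over anterior Chia at least 617-fold) and a lobe cell held by whole glands in the same ratio to melanotroph-like cells (0.0161 of the predicted UMIs).

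Immediate early genes were higher in folliculostellate-like than in pituicyte-like cells. Separate handling of the dissected lobes is unlikely to be the whole cause, because the list had a median log2 ratio of 5.17 within the whole-gland suspension and 4.35 between the dissected lobes. Low-depth pituicyte-like cells are also unlikely to be it, since 13 members were called higher without them (median 4.68). A difference in cell quality (median mitochondrial shares of 14.40% and 14.99% in the pituicyte-like and 10.87% to 11.68% in the folliculostellate-like clusters), a response of 1 cell class to dispersal, and a difference between the classes in the animal, stay open and were not tested.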

How the results depend on the processing

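The alternatives that left out hormone-rich or low-depth cells or the highest cell, and marker likelihood, were chosen only after the result was seen. Of 420 class shares under the alternatives, 75 moved beyond their interval; of 1972 counts of list members 78 moved; of 935 list tests 8 reversed, 9 became stronger and 39 weaker; of 4025 values of named genes 17 reversed, 13 became stronger and 19 weaker. Except for the class shares under the stricter cell filter, the cause was not tested for the changes below. That filter also lowered the mitochondrial limit. The median shares of the folliculostellate-like (10.87% to 11.68%) and pituicyte-like clusters (14.40% and 14.99%) lay above the lowered limit, so most of these cells failed it.

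The stricter cell filter gave folliculostellate-like shares of 6.45% (anterior), 4.56% (posterior) and 7.97% (whole) and pituicyte-like shares of 5.07% and 0.153%, too few for a pituicyte contrast; the looser filter gave 32.6% posterior pituicyte-like cells. Leaving out 1 library at a time gave 2873 to 4432 genes between folliculostellate-like and pituicyte-like cells, 1638 to 2722 higher and 1134 to 1868 lower. The astroglial list between these classes had an adjusted p of 0.289 with an estimated correlation, 0.0595 with UMIs split at random, 0.0652 with sums over both libraries and 0.0795 without hormone-rich cells. The cell cycle list of folliculostellate-like against hormone cells lost its call in the same settings (0.338, 0.0595, 0.067 and 0.116, in that order), with no preparation term (0.280), without lane 2 (0.271) and without the posterior library (0.0554). The stem list of pituicyte-like against hormone cells ranged from 0.0193 to 0.234 with 1 library left out.

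Genes higher in the anterior and the posterior library numbered 113 and 366 (endothelial), 95 and 249 (macrophage) and 82 and 172 (folliculostellate) at 2-fold, and 5 and 40, 4 and 12, and 4 and 8 at 200 UMIs. Per-cell means gave 38 anterior endothelial and 2 anterior folliculostellate genes. Without the highest cell 8 anterior folliculostellate genes met the rule (6 of them in the main list), 26 posterior ones (all in it) and 10 anterior macrophage genes (7 in it). Without hormone-rich cells 3 anterior folliculostellate genes met it. Cycling shares of folliculostellate-like cells were 3.49% (anterior) and 3.57% (whole) without thinning, 0.306% (posterior) and 0.878% (whole) at 1000 UMIs, and 0.491% (anterior) by marker likelihood. Those of whole-gland pituicyte-like cells were 0 of 86 in the main setting, 6.32% without thinning and 9.18% by marker likelihood. The lane correlation was 0.998 with CPM + 10.

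Tests that turned direction had no call. The junction list between the glia-like classes turned with the looser filter (0.964), doublets kept (0.981), no preparation term (0.867), both libraries (0.783) and without hormone-rich cells (0.945). With 1 library left out, adjusted p ranged from 0.299 to 0.997 (retinoid) and 0.364 to 0.954 (vascular) there, and from 0.690 to 0.919 for the cell cycle list of pituicyte-like against hormone cells. Sox9 between the glia-like classes was 0.029 with UMIs split at random, 0.026 without hormone-rich cells, 0.00322 without the low-count filter, 0.00496 with both libraries, 0.040 with the compared classes alone, and -0.126 to 0.028 with 1 library left out; Sox2 was -0.051 to 0.291. Against hormone cells, Six6 in folliculostellate-like cells was -0.42 (stricter filter) and -0.052 (UMIs split at random), and Stra6 was -0.35 (UMIs split at random) and -0.075 (DESeq2). In pituicyte-like cells Adcyap1r1 was -0.23 (UMIs split at random) and Timp1 -0.070 (both libraries). With 1 library left out, Adcyap1r1 ranged from -0.25 to 1.53. Hey2 and Nrarp counted as reversed without the posterior library, but pituicyte-like cells then had 0 UMIs of either, so the fitted -4.23 (Hey2) and -5.76 (Nrarp) show no turn in direction. With any other library left out Hey2 ranged from 2.24 to 3.53 and Nrarp from 1.98 to 2.68. DESeq2 and the setting without possible free RNA gave no list test.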

Other observations

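Hormone RNA was also seen in classes that do not make it, which no comparison was set up to ask about. Pomc stood at 839 CPM in dissected and 1368 CPM in whole-gland folliculostellate-like cells, against 441397 and 427784 CPM in melanotroph-like cells. Of the Pomc UMIs in folliculostellate-like cells, 3953 of 7225 anterior and 14351 of 20873 whole-gland ones lay in the hormone-rich sub-cluster 3. Gh1 stood at 6080 and 9965 CPM in folliculostellate-like cells, mostly from the same sub-cluster (38447 of 52336 anterior and 132622 of 152083 whole-gland UMIs). In the whole class Cga stood at 265 and 854 CPM, Lhb at 25.6 and 72.4 CPM, Tshb at 14.6 and 68.3 CPM and Fshb at 1.16 and 2.88 CPM. In pituicyte-like cells Prl stood at 3654 and 5999 CPM, Avp at 72.6 and 129 CPM and Oxt at 53.1 and 86.2 CPM.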
